A study of Mus musculus with 6 samples.

How the data were processed

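Total RNA of the epithelial fraction washed from mouse colon was sequenced in 6 libraries, 3 wild type and 3 Lingo2 mutant, from mice aged 2 months. Per the labels' protocols, libraries were made with a stranded total RNA kit that removes ribosomal RNA. Per the submitters' processing notes the tools were Trimmomatic 0.39, STAR, HTSeq and DESeq2, with genome build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands are uncertain.

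The deposited count table holds whole-number read counts per gene for each library, not normalized, followed by 5 summary lines of the counting tool. Those lines name no gene and were left out of library sizes and tests. Reads in no annotated feature made up 18.5% to 22.1% of all alignments counted in the table in wild type and 23.6% to 27.6% in mutant libraries. Ambiguous reads made up 1.23% to 1.28% and 1.34% to 1.57%, and alignments that were not unique 36.5% to 36.9% and 30.8% to 33.9%. A second deposited table holds the authors' own comparison. Its normalized signal per library equals the count times 1 factor per library in 100% of values at a relative tolerance of 1e-06, and its mean signal, log2 fold change with standard error, test score and p-value columns carry the authors' column names. From it were used the adjusted p-values, the direction of the authors' log2 fold changes, the normalized values for that check of factors, and gene symbols that the reference lacked.

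Gene reads numbered 25010618 to 28029583 in wild type and 7060769 to 13047682 in mutant libraries, so low genes are measured less precisely in the mutant libraries. A count of 0 allows up to 3 reads, which is 0.112 to 0.138 CPM per wild type library and 0.207 to 0.374 CPM per mutant library. Intervals and floors cover counting error only. Symbols, positions and transcript sequences came from GENCODE M21 (GRCm38), which with its table of gene names gave symbols to 45229 of 46078 gene rows. A further 3 rows took their symbol from the authors' deposited comparison alone, and 846 had none.

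Counts were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM factors, robust dispersions and the quasi-likelihood F test on genotype, over 16757 genes. P-values were adjusted by Benjamini-Hochberg and the threshold was 0.05. Adjusted p-values called edgeR adjusted p come from this test. Errors after log2 fold changes are standard errors computed as the fold change divided by the square root of F, and errors after CPM are SDs over 3 libraries. The script was tested on simulated counts with 200 changed genes for the comparison of mutant and wild type over 16757 genes. It recovered 68% of 100 genes changed 2-fold and 93% of 100 genes changed 4-fold, with 18 false calls. These false calls were a larger share of all calls than the threshold of 0.05 allows on average. The simulated genes varied independently, with no shared effect of library or batch, which the real data may hold.

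Before the data were examined, 37 gene lists were fixed for epithelial cell types, other cell types, signalling, stress, gut region and metabolism, and 36 had the minimum of 3 tested members. The list of Y-linked and X-inactivation genes had 1 tested member, Xist (0.13), and was not tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. A directional fry p tests whether a list moves on balance to 1 side. Several lists share members with the studied epithelium or with each other, such as Retnlb, Clca1 and Ang4 in the goblet and type 2 lists.

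The rule for named genes was also fixed before the data were examined. It takes Lingo2, Tff1, Tff2, Tff3 and Egfr, then the 12 largest rises and 12 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and groups that do not overlap, then up to 4 called members of each list, or up to 2 members with the smallest p where none was called. A gene that the rule takes is not reported here. Genes outside this rule are named as chosen after their values were seen. The 5 genes near Lingo2 are all the called genes in that window.

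Replicates were compared by a chi-square test of their counts over genes, which gave 8.40 to 19.4 per degree of freedom, so no pair of libraries agreed within sampling noise. Principal component 1 held 41.9% of the variance of log2 CPM (prior count 2) and separated the genotypes. Pearson's r across genes, which are not independent replicates, was 0.984 to 0.988 within wild type, 0.979 to 0.981 within mutant and 0.968 to 0.982 between genotypes.

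Alternatives fixed in advance were DESeq2 size factors, upper quartile factors, no filter, a filter at 1 CPM in 3 libraries, a replicate block, leaving out mitochondrial, haemoglobin and immunoglobulin genes, dispersions that are not robust, limma voom with sample weights, the DESeq2 1.42.0 Wald test, glmTreat at a fold of 1.2, other thresholds, and leaving out each library. Chosen after seeing the data were thinning every library to the smallest total, offsets for transcript GC content and length (known for 99.5% of tested genes), leaving out the 10 most counted genes, and keeping mutant replicate 1 as the only mutant library. Transcripts of genes changed more than 8-fold were searched against all M21 transcripts with BLAST 2.17.0+, calling a copy near-identical at 95% identity over 80% of the length.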

Results

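RNA was sequenced from the epithelial fraction of the mouse colon, in 3 wild type and 3 Lingo2 mutant libraries. The fraction is the cells released from the tissue by a wash with EDTA and DTT. The mice were aged 2 months and were not challenged. The comparison asks which transcripts of this fraction differ when Lingo2, a leucine-rich repeat and immunoglobulin domain membrane protein, is disrupted. Reads on genes numbered 25010618 to 28029583 in the wild type libraries and 7060769 to 13047682 in the mutant libraries. Every mutant library was shallower than every wild type library. Mitochondrial genes took 45.3% to 48.4% of gene reads in the wild type libraries and 35.7% to 39.8% in the mutant libraries, most of them from the ribosomal RNA mt-Rnr2. The rRNA-like transcripts Gm26917 and Gm42418 together took 1.27% to 1.59% and 1.69% to 3.51%. The labels give replicate numbers and do not say that the libraries came from separate animals. The p-values therefore measure the spread between these libraries, which may be technical.

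**Figure D1:**
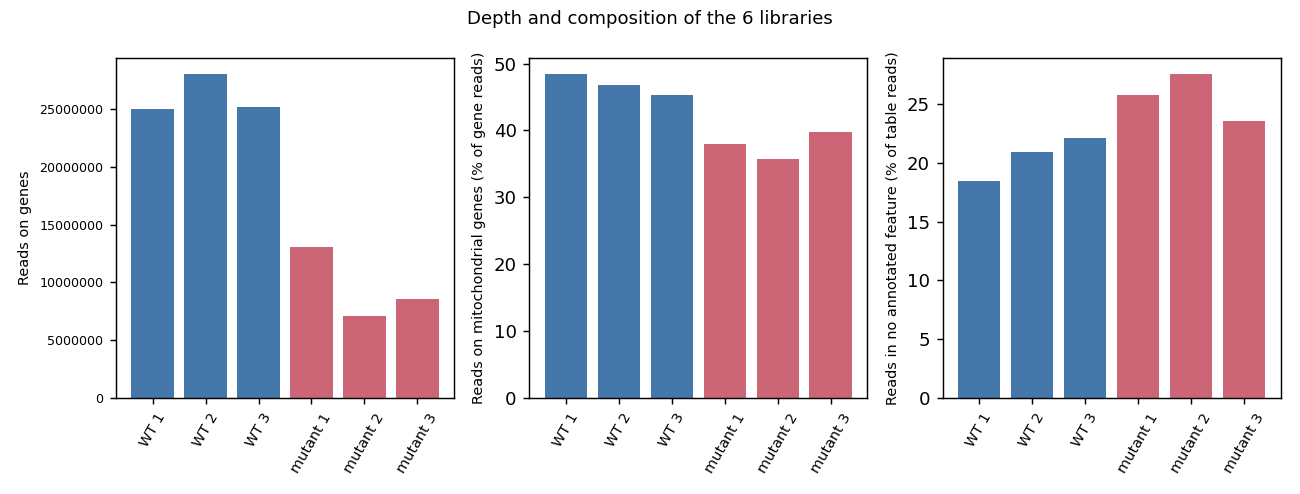
Bars give, for each of the 6 libraries, the reads on genes and the percentage of gene reads on mitochondrial genes. The last panel gives the percentage of all counted alignments, named table reads on its axis, that fell in no annotated feature. Blue is wild type (WT) and red is Lingo2 mutant. Wild type libraries held 25010618 to 28029583 gene reads and mutant libraries 7060769 to 13047682, with 45.3% to 48.4% and 35.7% to 39.8% of them mitochondrial.

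Lingo2 itself was barely detected in either genotype. The gene (chromosome 4, 35706647 to 36951747, minus strand, GRCm38) had 0, 7 and 0 reads in wild type replicates 1, 2 and 3 and 1, 1 and 0 reads in mutant replicates 1, 2 and 3. In CPM, the usual scaling of counts to library size, here pooled by genotype, this was 0.0972 in wild type (95% exact Poisson interval 0.0391 to 0.2002) and 0.0642 in mutant libraries (0.00777 to 0.232). These intervals cover counting error only. A difference was not detectable at this depth, Lingo2 was not tested, and its reads do not check the genotype labels. Of the trefoil factors, small secreted peptides that protect the mucosa, Tff3 stood at 311 ± 89.0 CPM (SD, n = 3) in wild type and 249 ± 41.9 CPM in mutant libraries (log2 fold change −0.32 ± 0.23, SE, edgeR adjusted p = 0.494). Tff2 was at 0.767 ± 0.0521 and 0.298 ± 0.1005 CPM (−1.25 ± 0.43, edgeR adjusted p = 0.146), and Tff1 was below the filter. The list of the Lingo family and trefoil factors had 3 tested members, none past the test over all genes, and 1 fell, Tff2, when adjusted over the list alone (median −0.32, camera adjusted p = 0.228). Tff2 had 6, 2 and 2 reads in mutant replicates 1, 2 and 3, so its level in these shallower libraries lay near the floor.

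Transcripts of T cells and intraepithelial lymphocytes, the lymphocytes that lie within the gut epithelium, were lower in the mutant libraries, with 18 of 20 listed genes fallen and a median log2 fold change of −1.56 over the list. Several regulators and products of goblet cells, the mucus-secreting cells of the epithelium, were higher, among them Spdef (0.84 ± 0.10), Atoh1 (0.90 ± 0.11) and Spink4 (1.01 ± 0.16). The interferon-induced genes Mx1 (1.15 ± 0.10) and Oas2 (1.00 ± 0.13) also rose. Over the whole transcriptome 430 of 16757 tested genes changed, 175 higher and 255 lower in the mutant libraries, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 181 changed more than 2-fold, 47 higher and 134 lower. The count of changed genes fell to 174 without mutant replicate 2 and 180 without mutant replicate 3, and rose to 674 without wild type replicate 3. Those over 2-fold then numbered 112, 93 and 363.

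In the T cell and intraepithelial lymphocyte list the cytotoxic granule proteases fell most. Gzma went from 102 ± 17.3 to 18.9 ± 4.04 CPM (−2.42 ± 0.18, edgeR adjusted p = 0.000294) and Gzmb from 57.3 ± 5.75 to 11.8 ± 3.60 CPM (−2.25 ± 0.19, edgeR adjusted p = 0.000588). Cd7, a lymphocyte surface protein, fell from 29.0 ± 3.62 to 6.87 ± 0.168 CPM (−2.08 ± 0.13), and Cd3g, a chain of the T cell receptor complex, from 30.3 ± 0.738 to 7.62 ± 1.55 CPM (−1.99 ± 0.13). Nkg7, a cytotoxic granule protein, fell by 1.84 and Itgae, the integrin chain that binds E-cadherin on epithelial cells, by 1.17 on the log2 scale. The receptor constant genes Trdc (−1.90 ± 0.26) of the delta chain and Tcrg-C1 (−2.12 ± 0.30) of the gamma chain and the chemokine Xcl1 (−1.87 ± 0.26) were also lower. The call of Tcrg-C1 ended without mutant replicate 2 (edgeR adjusted p = 0.0556) or 3 (0.0509), and at least 15 members of the list fell whichever library was left out. Adjusting over the list alone, which could not remove any of these 18 calls in so short a list, added none. The list passed camera (adjusted p = 2.19e-84), with an adjusted p = 0.0247 with an estimated correlation and a directional fry adjusted p of 0.00285. The mean log2 CPM of the list was 3.86, 4.04 and 4.02 in the wild type libraries and 2.64, 2.51 and 2.27 in the mutant libraries.

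Goblet cell genes rose in 5 of 20 members, and in 11 when adjusted over the list alone, with no member fallen and a median of 0.39. Spdef, a transcription factor of goblet cell maturation, rose from 67.6 ± 3.94 to 121 ± 13.3 CPM (edgeR adjusted p = 0.000990), and Atoh1, the transcription factor that commits cells to the secretory lineage, from 27.0 ± 1.68 to 50.6 ± 6.77 CPM (edgeR adjusted p = 0.00115). Spink4, a secreted goblet cell protein, rose from 264 ± 24.1 to 530 ± 134 CPM (edgeR adjusted p = 0.00905), and the transcription factor Foxa3 rose by 0.59 ± 0.12. Members with larger fitted values but a wide spread did not pass, as Ang4 (2.39 ± 0.47, edgeR adjusted p = 0.0818), Retnlb (2.90 ± 0.65, edgeR adjusted p = 0.113) and Clca1 (1.13 ± 0.33, edgeR adjusted p = 0.129), which are secreted products. These 3 were chosen after their values were seen, and Ang4 passed without wild type replicate 3 (2.07, edgeR adjusted p = 0.00470) and Clca1 without wild type replicate 1 (1.501, edgeR adjusted p = 0.0236). Camera called the goblet list (adjusted p = 5.39e-09), and the call was lost with an adjusted p = 0.538 with an estimated correlation. The crypt stem cell and Wnt target list had 2 of 17 members higher, Rgmb (0.60 ± 0.10), a BMP co-receptor, and Sox9 (0.75 ± 0.13), a crypt base transcription factor, and 2 when adjusted over the list alone (camera adjusted p = 0.00527, adjusted p = 0.736 with an estimated correlation). The goblet list had 3 genes risen without mutant replicate 3, and 3 risen and 1 fallen, Zg16, without wild type replicate 2. Foxa3 lost its call without wild type replicate 2, mutant replicate 1 or mutant replicate 3 (edgeR adjusted p = 0.0587 to 0.0861), and Sox9 without mutant replicate 2 or 3 (0.0581 and 0.0584). In the enteroendocrine list 1 of 17 genes fell, Gcg, the proglucagon gene (−0.71 ± 0.12; median of the list −0.29, camera adjusted p = 0.0342 and adjusted p = 0.736 with an estimated correlation). Camera no longer called that list without wild type replicate 1 (adjusted p = 0.0722, median −0.16), wild type replicate 2 (0.0944) or mutant replicate 3 (0.3905, median −0.13).

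Other epithelial lists had no member past the test. Tuft cell genes had a median of 0.14 over 17 genes (camera adjusted p = 0.0469, adjusted p = 0.736 with an estimated correlation). The tuft median ranged from 0.07 without wild type replicate 3 to 0.31 without mutant replicate 1, and camera's call ended without wild type replicate 3 (adjusted p = 0.332) or mutant replicate 3 (0.175). Trpm5, a tuft cell cation channel, was at 0.40 ± 0.11. Proliferation genes had a median of −0.18 over 21 genes (camera adjusted p = 0.0469, adjusted p = 0.737 with an estimated correlation). Camera's call of proliferation genes ended without wild type replicate 2 (adjusted p = 0.232), wild type replicate 3 (0.0784), mutant replicate 1 (0.704) or mutant replicate 2 (0.0595). The replication factor Mcm3 was at −0.40 ± 0.12 and Pcna at −0.30 ± 0.09. Epithelial identity genes (median 0.04 over 16 genes), junction genes (−0.08 over 20) and absorptive colonocyte genes (−0.25 over 22) did not pass camera, with adjusted p-values of 0.642, 0.601 and 0.288. Small intestine genes, 14 tested and none passed, had a median of 1.16 (camera adjusted p = 0.00836, adjusted p = 0.736 with an estimated correlation). This median was 0.74 without mutant replicate 2 and 0.32 with mutant replicate 1 as the only mutant library, and camera's call ended without wild type replicate 1 (adjusted p = 0.0623). The 6 tested Hox genes of the distal colon had a median of 0.09 (camera adjusted p = 0.631).

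**Figure D2:**
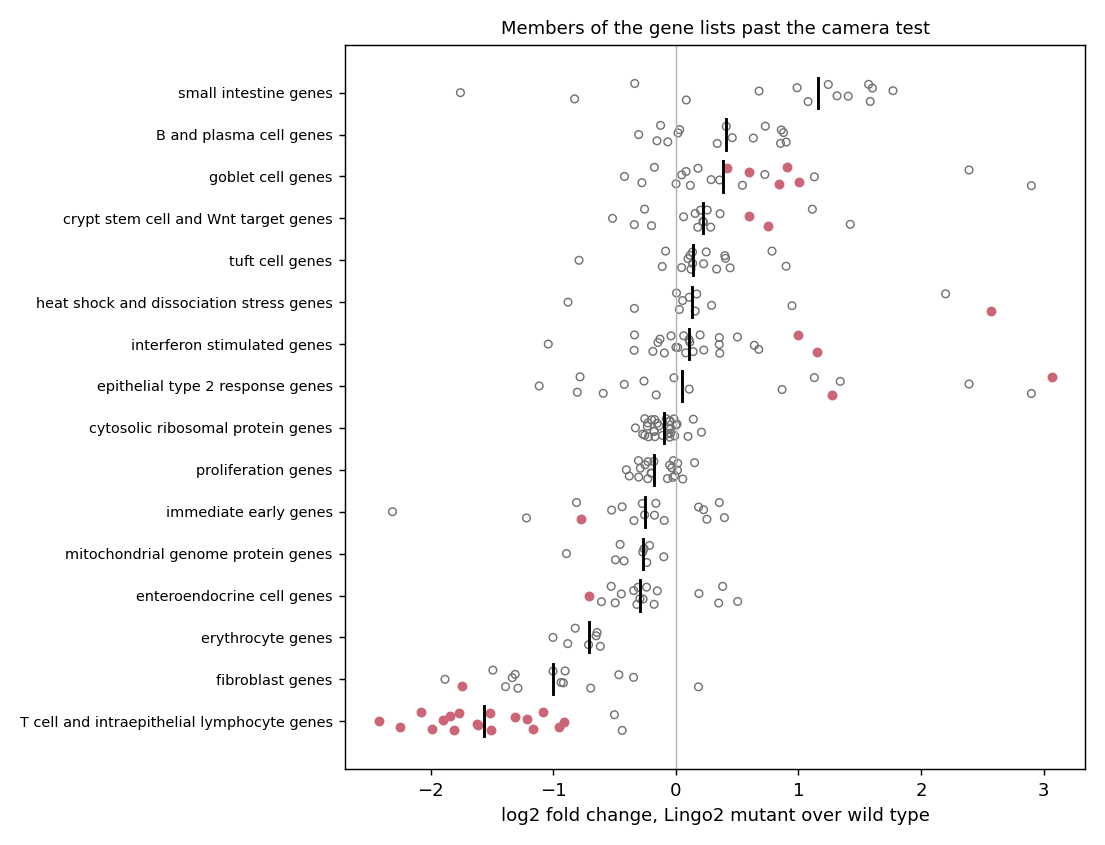
Each point is the log2 fold change of 1 tested gene, mutant over wild type, for the 16 lists past camera with the preset correlation; filled red points passed edgeR's test over all genes, open points did not, and the black bar is the list's median. The T cell and intraepithelial lymphocyte list, with 18 of 20 genes past the test and a median of −1.56, is the 1 list also called with an estimated correlation.

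In the epithelial type 2 response list, genes induced by interleukins of the type 2 response, 2 of 16 members rose, the intelectin Itln1 (3.07 ± 0.34) and the gasdermin Gsdmc3 (1.27 ± 0.23). Adjusted over the list alone 6 rose and 3 fell, and the median of 0.05 lay far below the mean of 0.56 (camera adjusted p = 0.010002, adjusted p = 0.736 with an estimated correlation). When wild type replicate 2 was left out no member rose, Sprr2a1 and Sprr2a2 fell, the median was −0.08 and camera's call ended (adjusted p = 0.120). The call of Itln1 also ended without wild type replicate 1 (edgeR adjusted p = 0.0720), and that of Gsdmc3 without any 1 mutant library (0.122 to 0.149). The median was below 0 without wild type replicate 3 (−0.011) or mutant replicate 3 (−0.07) as well. Interferon stimulated genes rose in 2 of 25 members, Mx1 and Oas2, and in 6 when adjusted over the list alone, where 2 fell (median 0.11, camera adjusted p = 0.0164, adjusted p = 0.736 with an estimated correlation). Camera's call of the interferon list ended without wild type replicate 1 (adjusted p = 0.0933), wild type replicate 3 (0.137) or mutant replicate 3 (0.154), with medians of 0.0093, 0.06 and 0.017. Mx1 went from 21.7 ± 0.464 to 48.2 ± 4.17 CPM (edgeR adjusted p = 0.000129). Among 18 antimicrobial and inflammatory genes the secreted phospholipase Pla2g2a rose (1.68 ± 0.28), while Ido1, which degrades tryptophan (−1.50 ± 0.28), and the NF-kappaB inhibitor Nfkbia (−0.42 ± 0.09) fell. Ido1 lost its call without mutant replicate 1 or 3 (edgeR adjusted p = 0.0896 and 0.116), and Nfkbia without wild type replicate 2 or any 1 mutant library (0.0629 to 0.118). Adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.514). None of the 16 antigen presentation genes passed (median −0.17; 1 rose and 3 fell when adjusted over the list alone, camera adjusted p = 0.183).

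Of the lists of other cell types, the B and plasma cell list alone had a median above 0. Of the macrophage and dendritic cell genes 3 of 15 fell, Itgax (−0.99 ± 0.20), Tyrobp (−1.11 ± 0.24) and Ccr2 (−1.03 ± 0.23). No further member was called when adjusted over the list alone, and the median was −0.12 (camera adjusted p = 0.0992). None of the 3 genes Itgax, Tyrobp and Ccr2 fell without wild type replicate 2, mutant replicate 2 or mutant replicate 3 (medians −0.13, −0.37 and 0.04). Of them 1 fell without wild type replicate 3 or mutant replicate 1, and 2 without wild type replicate 1. B and plasma cell genes had a median of 0.41 and none of 15 passed (camera adjusted p = 0.0195, adjusted p = 0.736 with an estimated correlation). Their median was 0.24 without wild type replicate 1 and 0.23 without wild type replicate 3, where camera's call ended (adjusted p = 0.155 and 0.131), and 0.64 without wild type replicate 2, where 4 rose. Igha, the constant region of IgA, was at 0.73 ± 0.23. Fibroblast genes had a median of −1.002, with the matrix protein Mfap5 fallen (−1.75 ± 0.39). Mfap5 lost its call without wild type replicate 1, wild type replicate 2, mutant replicate 2 or mutant replicate 3 (edgeR adjusted p = 0.1002 to 0.151). The fibroblast median was −1.52 without mutant replicate 2, and 3 members fell without wild type replicate 3. Adjusted over the list alone 2 of 15 fell (camera adjusted p = 0.000147, adjusted p = 0.736 with an estimated correlation). All 7 erythrocyte genes lay below 0 (median −0.71) and none passed, although 2 fell without wild type replicate 2. Of these, 5 fell when adjusted over the list alone (camera adjusted p = 0.000185, adjusted p = 0.736 with an estimated correlation). In the endothelial list Vwf, the von Willebrand factor gene, rose (0.96 ± 0.18) among 8 genes with a median of −0.41 (camera adjusted p = 0.642), and lost its call without wild type replicate 2 or any 1 mutant library (edgeR adjusted p = 0.0522 to 0.0719). No member passed in the smooth muscle list (median −0.29, camera adjusted p = 0.0936), the granulocyte and mast cell list (−0.29, camera adjusted p = 0.358) or the enteric neuron and glia list (−0.23, camera adjusted p = 0.668).

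**Figure D3:**
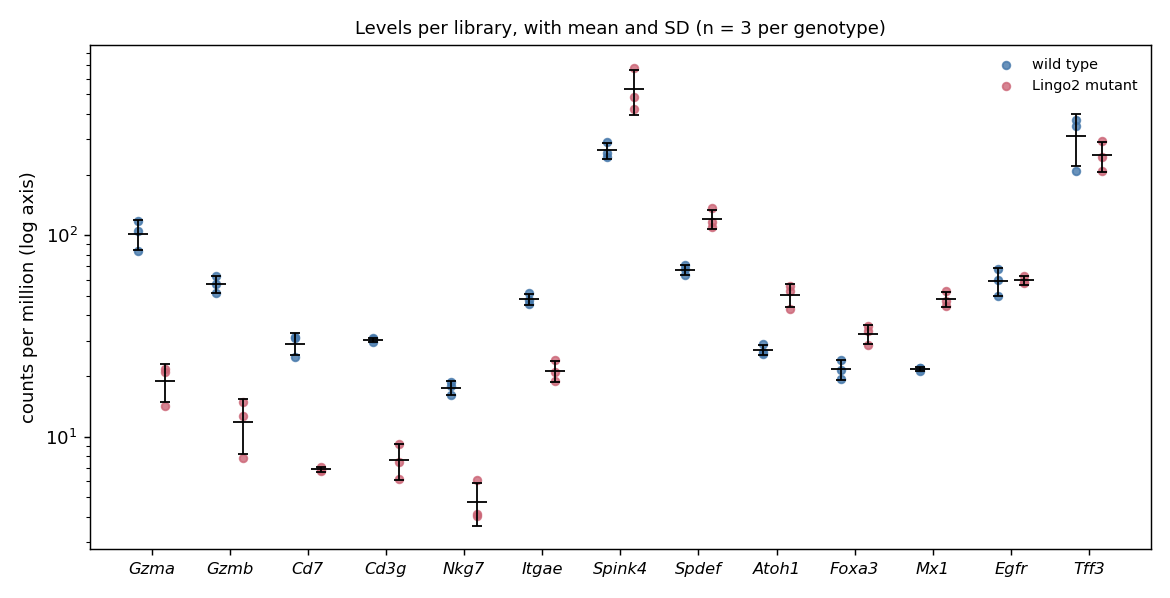
CPM on a log axis for 13 named genes in the 3 wild type (blue) and 3 Lingo2 mutant (red) libraries, with the mean and SD of each genotype in black. The lymphocyte genes Gzma (102 to 18.9 CPM) through Itgae were lower and the goblet cell genes Spink4 (264 to 530 CPM) through Foxa3 higher in every mutant library than in every wild type library, while Egfr and Tff3 overlapped.

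Egfr, the epidermal growth factor receptor, stood at 59.3 ± 9.15 CPM in wild type and 59.7 ± 2.80 CPM in mutant libraries (0.01 ± 0.11, edgeR adjusted p = 0.970), and the fitted value was below 0 with upper quartile factors (−0.01), without wild type replicate 2 (−0.10) and without mutant replicate 1 (−0.04). None of the 13 tested genes of the EGFR family, its ligands and its feedback passed (median −0.07, camera adjusted p = 0.587). Erbb3 was at −0.32 ± 0.11 and the feedback protein Lrig1 at 0.26 ± 0.09. Of 17 genes read out from the ERK pathway, Myc (0.72 ± 0.15, edgeR adjusted p = 0.0266) and Etv4 (0.90 ± 0.20, edgeR adjusted p = 0.0394), both transcription factors, rose. Neither was called without wild type replicate 1, wild type replicate 2, mutant replicate 1 or mutant replicate 3 (edgeR adjusted p = 0.0569 to 0.1502), nor was Myc without mutant replicate 2 (0.0535). Adjusted over the list alone 2 rose and 1 fell (median 0.05, camera adjusted p = 0.484). Immediate early genes, which respond within minutes to stimuli and handling, had Nr4a1 fallen (−0.78 ± 0.14) among 17 and 3 fell when adjusted over the list alone (median −0.26, camera adjusted p = 0.0333, adjusted p = 0.736 with an estimated correlation). Nr4a1 lost its call without mutant replicate 2 or 3 (edgeR adjusted p = 0.0689 for both). For this list camera's call ended without wild type replicate 3 (adjusted p = 0.749, median −0.03), mutant replicate 1 (0.433) or mutant replicate 3 (0.0811). Among 12 heat shock and dissociation stress genes Hspa1a, an inducible chaperone, rose from 1.65 ± 0.527 to 9.72 ± 3.85 CPM. In this list 2 rose and 1 fell when adjusted over the list alone (median 0.13, camera adjusted p = 0.0333, adjusted p = 0.736 with an estimated correlation). Camera did not call it without wild type replicate 2 (adjusted p = 0.0753), wild type replicate 3 (0.225) or mutant replicate 1 (0.160), and the median ranged from 0.035 without mutant replicate 3 to 0.20 without wild type replicate 1.

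The clock, metabolic, housekeeping and mitochondrial lists had medians from −0.27 to 0.05, which can hide members that move in opposite directions. Fry's mixed test, of change in either direction, called 3 of them. These were the clock (fry mixed adjusted p = 0.00157), xenobiotic (0.00800) and oxidative phosphorylation lists (0.0252), and the others in this paragraph were not called. The circadian repressors Nr1d1 (−1.02 ± 0.19) and Nr1d2 (−0.45 ± 0.10) fell among 15 clock genes (median −0.05; 2 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.566). In oxidative phosphorylation Ndufa4 fell (−0.57 ± 0.10) and Cox5a rose (0.51 ± 0.11) among 24 genes (median 0.05, camera adjusted p = 0.642). Among 21 xenobiotic metabolism genes the drug efflux pump Abcb1a (−0.71 ± 0.13) and the aryl hydrocarbon receptor repressor Ahrr (−1.36 ± 0.27) fell and the cytochrome Cyp2b10 rose (2.24 ± 0.45). Adjusted over the list alone 3 rose and 5 fell (median −0.20, camera adjusted p = 0.0992). Each of these 7 calls in the clock, oxidative phosphorylation and xenobiotic lists ended without mutant replicate 2 or 3 (edgeR adjusted p = 0.0604 to 0.127). Those of Nr1d2, Cox5a, Ahrr and Cyp2b10 ended without wild type replicate 2 (0.0554 to 0.106), that of Cox5a without wild type replicate 1 (0.0760) and that of Ahrr without mutant replicate 1 (0.0641). Cytosolic ribosomal protein genes had a median of −0.09 and none of 30 passed (camera adjusted p = 0.0275, adjusted p = 0.737 with an estimated correlation), and camera's call ended without wild type replicate 3 (adjusted p = 0.137) or mutant replicate 2 (0.331, median −0.04). The 9 tested protein genes of the mitochondrial genome all lay below 0 (median −0.27, and −0.16 without wild type replicate 1) and none passed (camera adjusted p = 0.00527, adjusted p = 0.736 with an estimated correlation), in libraries that also held a smaller share of mitochondrial reads. No member passed among genes of cholesterol synthesis (median −0.15), butyrate and fatty acid oxidation (0.01) or the unfolded protein response (0.02), with camera adjusted p-values of 0.0992, 0.642 and 0.642.

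The largest single changes were near presence and absence. Cylc2 (chromosome 4, 51216678 to 51230272), which encodes a sperm head cytoskeletal protein, had 1 read over the wild type libraries and 556 over the mutant libraries, a depth-scaled ratio of 1285 (95% exact interval for the counts 229.7 to 50839). The processed pseudogene Gm4760 on chromosome X had 2 and 439 reads, a ratio of 507 (140 to 4202). Hist1h4m, a histone H4 gene on chromosome 13, went the other way with 579 and 4 reads (−5.89 ± 0.33, edgeR adjusted p = 5.61e-06). It has near-identical copies whose reads cannot be separated with certainty. The lipase Pnliprp2 (4.02 ± 0.46), Gm47283 on chromosome Y (4.65 ± 0.42), the colipase Clps (1.90 ± 0.33) and the phospholipase Plcd3 (1.81 ± 0.19) rose. Gm47283 matches Gm21887 at 98.5% identity over 57.3% of its length. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were below the filter. Xist stood at 1015 ± 147 CPM in wild type and 1112 ± 72.2 CPM in mutant libraries. The rise of Gm47283 is therefore not read as a change of Y-linked expression. The small nuclear and nucleolar RNA genes Gm22973, Snord22 and Snora23 rose by 1.95, 1.93 and 1.80. The peptide transporter Slc15a2 (−3.42 ± 0.46), the growth factor Igf1 (−2.48 ± 0.35), the synaptic protein Rims2 (−2.19 ± 0.39) and the interferon-inducible Ifi208 (−1.94 ± 0.40) fell. Calls of Pnliprp2, Clps, Gm22973 and Snord22 ended without wild type replicate 1 or 2 (edgeR adjusted p = 0.0533 to 0.126), and those of Igf1, Rims2, Snord22 and Snora23 without any 1 mutant library (0.0534 to 0.141). Snora23 and Ifi208 also lost theirs without wild type replicate 1 (0.115 and 0.0720), Clps without wild type replicate 3 (0.0688), Ifi208 without mutant replicate 2 or 3 (0.111 and 0.0925) and Slc15a2 without wild type replicate 2 or mutant replicate 3 (0.0673 and 0.127). Within 20 Mb of Lingo2 5 of 191 genes were past the test (2.62%) against 2.56% elsewhere (two-sided Fisher's exact test, p = 0.819). Within 5 Mb these were 3 of 59 (5.08%) against 2.55% elsewhere (two-sided Fisher's exact test, p = 0.192), Bach2 (0.85), Pnrc1 (−0.41) and Spink4 (1.01), and the wider window added Stx17 (0.46) and Cylc2.

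Groups did not overlap for any of the 430 called genes, nor for 24.1% of all tested genes, where chance gives 10% for 3 against 3. With the preset correlation of 0.01 camera called 16 of 36 lists, 8 higher and 8 lower, and 10 without wild type replicate 3. With an estimated correlation, and with fry's directional test, 1 list was called, the T cell and intraepithelial lymphocyte list. No list's median, mean and camera direction differed in sign. Depth, the mitochondrial share and genotype separate the libraries in the same way. Other divisions of the 6 libraries, which mix the genotypes, gave up to 15 lists past camera.

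The authors' deposited table of their own comparison held 14338 genes, of which 675 had an adjusted p under 0.05, 273 higher and 402 lower in the mutant libraries. Of the 430 genes called here by edgeR, 402 were past that threshold in the authors' deposited table, all 402 in the same direction, and 20 were absent from it.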

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

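Tests chosen only after the result was seen are those on the yield of non-epithelial cells, libraries out of place, the epithelial share, the colon region, linkage to Lingo2 and the summed histone genes, and the thinned and GC-corrected fits were added after the data had been seen.

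Reads in no annotated feature, which no comparison used, averaged 25.6% of all counted alignments in the mutant libraries and 20.5% in wild type, above the highest wild type library in each mutant library. With mitochondrial reads and alignments that were not unique left out of the total, these shares were 43.9% to 48.9% in wild type and 47.1% to 50.2% in mutant libraries. The lowest mutant library then lay 1.76 percentage points under the highest wild type library (−1.76). Ambiguous reads averaged 1.44% in mutant and 1.25% in wild type libraries, also above every wild type library.

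For the lower level of T cell and intraepithelial lymphocyte genes, the median was −1.60 after every library was thinned to the smallest total. Thinning keeps the expected share of each gene, so it could hardly move the median and does not decide on depth. GC content and transcript length are argued against by a median of −1.57 with offsets for both. A lower yield of all non-epithelial cells would lower the markers of each type alike. From wild type to mutant, though, the change of the B and plasma cell list lay above that of the T cell list. The difference of these changes was 1.95 ± 0.29 (SE) on the log2 scale. That list alone among those of other cell types had a median above 0, and its wild type libraries spread widely (1.84, 2.81 and 2.10 log2 CPM). A lower yield of some other cells together with T cells stays open. The change of the T cell list lay less far under those of macrophage (1.25 ± 0.20), erythrocyte (0.77 ± 0.31) and fibroblast genes (0.56 ± 0.53). The low-count genes Lama2 (−2.79), Fbln5 (−2.39), Hgf (−2.21) and Eln (−1.71), chosen after their values were seen, also fell by edgeR's test, but none of them without mutant replicate 3 (edgeR adjusted p = 0.0704 to 0.1498), and with any other library left out at least 1 of them did not pass or, for Hgf, was not tested. The highest mutant list mean lay under the lowest wild type mean (difference −1.22), which restates the fall of 18 of the 20 genes. The SDs of the list mean were 0.099 in wild type and 0.19 in mutant libraries. If the level follows genotype, 1 wrongly named library would lie among the libraries of the other genotype. None did, but that separation comes with the fall of those 18 genes, so it cannot decide on a wrong name. A wrong name of 1 library or an exchange of all names stays open. So do a smaller number of intraepithelial lymphocytes in the mutant epithelium, a difference in the wash and any batch that follows genotype, which were not tested.

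For the goblet cell genes the median was 0.37 after thinning, which for the same reason does not decide on depth. From wild type to mutant the goblet list rose 0.57 ± 0.10 (SE) more on the log2 scale than the epithelial identity list. This argues against a higher share of all epithelial cells. More proximal colon in the mutant washes cannot be told apart from a change in goblet cells, because 3 of the 6 tested distal Hox genes lay below 0 and 3 above. In the other list of gut region, small intestine genes, 11 of 14 lay above 0 and 3 below (median 1.16). None of those 14 passed the test over all genes, and camera called their list (adjusted p = 0.00836) but not with an estimated correlation (0.736). An effect of genotype on the secretory lineage may also apply and was not tested. For Spink4, which lies within 5 Mb of Lingo2, sequence linked to the targeted locus stays open too.

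Of the 11 called genes that differed more than 8-fold, 8 higher and 3 lower, sequence linked to the targeted locus does not account for most, since 1 of 10 genes with a position, Cylc2, lay within 20 Mb of Lingo2, and it stays open for Cylc2. Of the 10 genes searched, 9 had no copy at 95% identity over 80% of the length, which argues against shared reads as the account of all. They stay open for Gm47283, which matches Gm21887 at 98.5% identity over 57.3% of its length, and for Gm5388, which matches Actg1 at 92.6% over 100%. Hist1h4m had 2 such copies, Hist1h4i and Hist1h4n. Its summed level with Hist1h4n, leaving out Hist1h4i, was 15.1 ± 0.344 CPM in wild type and 18.7 ± 8.61 CPM in mutant libraries (SD, n = 3). The difference was 3.59 ± 4.97 (SE), and the mutant sums ranged from 9.45 to 26.5 CPM. That spread is too wide to decide, so its fall may be reads counted at a copy. A difference in strain background was not tested.

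The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05 (the real division, 1 of 10, is the smallest share). The real division gave 430 changed genes and the highest other 10, and for genes changed more than 2-fold the counts were 181 and 10. For lists past camera the real division gave 16 and the highest other 15. The T cell list had a mean of −1.50 in the real division and at most 0.57 in size in the others, 7 of 9 of which still called it with the preset correlation. The goblet list had a mean of 0.58 in the real division and at most 0.36 in size in the others, and 5 of those 9 called it. Each other division puts both genotypes in each of its groups. A genotype difference would then widen the spread within groups and leave a smaller part between them. The counts, means and list calls of the other divisions therefore do not measure what arises by chance.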

How the results depend on the processing

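The thinned, GC-corrected and lone-library fits and the fit without the 10 most counted genes were chosen after seeing the data. Of 54 named calls, 38 were kept at an adjusted p under 0.05 in every refit with all 6 libraries that gave a value and 13 in every refit, and none changed sign. Other thresholds and glmTreat were applied to the counts of genes alone, not to the named calls. The 430 changed genes became 1493 without a filter, 655 by the DESeq2 Wald test (13415 adjusted p-values were NA), 921 at an adjusted p under 0.1 and 138 at 0.01. With mutant replicate 1 as the only mutant library, assumed to vary like wild type, fewer samples left 81. Without 1 library the range was 174 (without mutant replicate 2) to 674 (without wild type replicate 3). The 181 changes over 2-fold became 439 without a filter and 64 with the lone mutant library, and ranged from 93 (without mutant replicate 3) to 363 (without wild type replicate 3). The 16 lists past camera became 1 with an estimated correlation and 1 by fry's directional test (18 lists passed fry's mixed test of change in either direction), and 10 (without wild type replicate 3) to 16 without 1 library. Lingo2 stayed untested or not past the threshold in every setting. With the replicate number as a block 360 genes were called, 291 of them shared, but the numbers do not pair the samples (r = −0.13, 0.13 and −0.02 for numbers 1 to 3), and not every sample correlated best with its own number.

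Directions turned in results that were not past the threshold, and the cause was not tested. Egfr was −0.0078 with upper quartile factors, −0.0097 without a filter and −0.10 to 0.12 without 1 library, and Hoxd11 −0.15 to 0.41. Enteric neuron and glia genes had a mean of 0.37 without a filter and −0.58 to 0.28 without 1 library. With the lone mutant library the means were −0.064 for epithelial identity genes, 0.039 for xenobiotic metabolism genes and −0.028 for unfolded protein response genes. Without 1 library, means ranged from −0.043 to 0.067 for epithelial identity genes, −0.045 to 0.11 for unfolded protein response genes, −0.21 to 0.039 for absorptive colonocyte genes and −0.13 to −0.027 for junction genes. They ranged from −0.23 to −0.080 for antimicrobial and inflammatory epithelial genes, −0.34 to −0.030 for endothelial cell genes, −0.028 to 0.062 for butyrate and fatty acid oxidation genes, −0.20 to 0.035 for antigen presentation genes and −0.031 to 0.067 for oxidative phosphorylation genes. The directions that turned are those of camera's test, which can differ in sign from the mean. Over the whole chromosome of Lingo2 2.23% of genes were called, under the 2.58% elsewhere. Depth limits what low genes of the mutant libraries can show.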

Other observations

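The genes in this part were chosen after their values were seen. All 7 tested T cell receptor constant genes fell, from −2.12 to −1.58, which covers alpha, beta, gamma and delta chains (Trac −1.77 ± 0.16, Trbc2 −1.70 ± 0.16, Tcrg-C4 −1.70 ± 0.19), and Trac and Trdc are also in the fixed list. The calls of Tcrg-C1 and Tcrg-C2 ended without mutant replicate 3 (edgeR adjusted p = 0.0509 and 0.0704), and that of Tcrg-C1 without mutant replicate 2 (0.0556). Among single genes outside the fixed lists, Il2rb (−1.52 ± 0.17), Cd69 (−1.53 ± 0.22), Klrd1 (−1.46 ± 0.26) and Klrk1 (−0.95 ± 0.21) fell, and Tbx21 did not pass (−0.76 ± 0.24, edgeR adjusted p = 0.124). The calls of Klrd1 and Klrk1 ended without wild type replicate 2 (edgeR adjusted p = 0.0727 and 0.0976) or mutant replicate 3 (0.143 and 0.0861), and that of Klrk1 also without wild type replicate 3 (0.0547), mutant replicate 1 (0.0889) or mutant replicate 2 (0.111). Cd4, the helper T cell co-receptor, stood at −0.50 ± 0.26 (edgeR adjusted p = 0.325), Foxp3, the regulatory T cell factor, at 0.60 ± 0.36 (edgeR adjusted p = 0.400) and the B cell gene Ms4a1 at 0.46 ± 0.40 (edgeR adjusted p = 0.596), although Ms4a1 rose without wild type replicate 2 (1.05, edgeR adjusted p = 0.0106).

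Rasa4, a regulator of Ras, rose from 32.8 ± 4.14 to 84.6 ± 8.95 CPM (edgeR adjusted p = 0.000129). Cracr2a (0.89 ± 0.10), Capn9 (0.93 ± 0.13), Kirrel3 (1.27 ± 0.18) and Hoxa5 (0.99 ± 0.18) rose too, and Hoxa5 lost its call without mutant replicate 2 (edgeR adjusted p = 0.0582).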
